A study of Mus musculus and Oryctolagus cuniculus and Macaca mulatta with 8 samples.

How the data were processed

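Hi-C libraries from primary liver cells of mouse, rabbit, macaque and dog, 2 per species, were grouped by the species in their labels. Per the file headers, the first column of values is the observed count of contacts for each pair of 50 kb bins. These counts are whole numbers, they are listed for both orders of a pair, and they cover pairs on the same chromosome up to 2 Mb apart. The deposited expected count is a signal from a bias model of the authors that is not described in the sources used here. From its values, it falls only slightly with distance, to between 0.947 (macaque 2) and 0.993 (dog 1) of its level at 100 kb by 1950 kb. At 2 Mb it drops to 0.498 to 0.500 of its level at 1 Mb, so distances below 2 Mb were used. Reads were aligned with Bowtie 0.12.8 per the submitters' processing notes, which name the builds mm10 and canFam3. The builds of rabbit and macaque are not given in the sources used here. The deposited merged files equal the sums of both libraries, with 0 pairs differing, and were not used further. A deposited summary gives, for each library, counts of total reads and of contacts within and between chromosomes.

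In units of M (mega), contacts between different bins numbered 6.88 and 26.0 M in mouse, 8.97 and 10.8 M in rabbit, 10.95 and 6.91 M in macaque, and 28.1 and 15.5 M in dog, for libraries 1 and 2. At this depth from 5.57% of the pairs of bins in dog 1 to 31.0% in mouse 1 held no contact, so contacts were summed over many pairs of bins. PCR duplicates cannot be told from independent molecules in these files, so intervals on shares of contacts cover counting error only.

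All values were computed in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and drawn with Matplotlib 3.10.9. The 2% of bins with the lowest coverage were left out. The decay exponent is the slope of log contact, observed over expected, against log distance from 100 kb to just under 2 Mb. Insulation of a bin is the log2 of the observed contacts in a diamond of 10 bins to each side, divided by the expected count and by the chromosome's own fall with distance, minus the chromosome mean. At least 50% of the pairs in the diamond had to be usable. A boundary is the lowest bin within 5 bins to each side, with a depth of at least 0.2 below the lower of the maxima within 10 bins to each side. Density is per 100 Mb of usable bins, and a boundary was shared when the other library had one within 1 bin. On simulated maps at least 93.9% of planted boundaries with contact at 0.5 or 0.7 of its level were recovered, and up to 16.1% of calls, at the depth of macaque 2, lay over 2 bins from any planted one. Maps without boundaries gave 69 and 74 calls on a chromosome at the depth of macaque 2, 34 and 43 at that of mouse 1 and 0 and 1 at that of dog 1.

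Species were compared by an exact permutation of labels over the 105 partitions of 8 libraries into pairs, with an F ratio as statistic and a smallest p of 0.00952. On 300 simulated data sets without a difference, 6.33% had p of 0.05 or less. Agreement of libraries and gene lists were tested against 1000 circular shifts along the chromosomes, one-sided for agreement and two-sided for gene lists, with a smallest p of 0.001. For a gene list the statistic of the shifts was its share near boundaries minus that of all genes, and for all genes the share itself. Gene lists were also tested with Fisher's exact test, two-sided, against all other measured protein-coding genes. The gene table was RefSeq on the mm10 chromosomes, and a gene was near a boundary when its lower coordinate lay within 1 bin. On X, windows of 10 Mb in steps of 1 Mb were matched to the best window of the other species in either orientation, and neighbours were collinear when their matches kept the step within 250 kb. Shares were averaged over both directions, and each X was ranked, one-sided, against the autosomes at least 0.5 times as long as the X searched. P-values were adjusted by Benjamini and Hochberg within each comparison.

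The regions named are, for each species, the 5 strongest reproducible autosomal boundaries, the strongest on X and the 3 longest intervals without a reproducible boundary among those with at least 80% usable bins. For each gene list the members named come from the 4 nearest to a boundary, and not every one of these is named. Cyp2e1, Rps6ka3, Rps6ka5 and the genes singled out inside long intervals fall outside this rule and were chosen after their values were seen. The naming rules, the measures, the gene lists and the main tests between species, between libraries, on X and at gene lists were chosen before the data were examined, but the form of the shift statistic for lists was not set then.

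Alternatives were minimum depths of 0.1 and 0.4, diamonds of 250 kb and 1 Mb, other distance ranges, leaving out 10% of bins, thinning to equal depth, no bias correction, permutation within replicate number, other windows and tolerances on X, and each library left out in turn. Further alternatives were added after the data were seen: boundaries deeper than 2 (log2) or near unusable bins left out, the upper gene coordinate, boundaries of a single mouse library, neighbouring genes counted once per bin, a stretched X profile, and a ribosomal list without kinases. Compartments were not analysed here because the files hold no contacts beyond 2 Mb. CTCF motifs were not analysed here because no genome sequence was at hand, nor were genes of the same symbol across species, since the gene table covers mouse. The 4C-seq experiments of the series were not analysed here.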

Results

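Hi-C, which counts how often pairs of genomic regions are ligated to each other in fixed nuclei, was measured in primary liver cells of young adult mouse (strain C57BL/6), rabbit, macaque and dog. There were 8 libraries, 2 for each of the 4 species. The files hold contacts between 50 kb bins of the same chromosome up to 2 Mb apart. In units of M (mega), contacts between different bins numbered 6.88 and 26.0 M in mouse libraries 1 and 2, 8.97 and 10.8 M in rabbit, 10.95 and 6.91 M in macaque, and 28.1 and 15.5 M in dog. The average pair of bins therefore held from 3.16 contacts in macaque 2 to 15.5 in dog 1. Contacts between chromosomes made up 16.7% of the library in rabbit 1 and 31.8% in dog 1, the lowest and the highest of the 8 libraries. The widest Wilson 95% interval of such a share, in macaque 2, reached 0.0173 percentage points to either side, for counting error only. No label states that the 2 libraries of a species came from separate animals. The p-values for differences among species therefore measure the spread between these libraries, which may be technical. The p-values from shifts, Fisher's exact test, the ranking of X against autosomes and the genes that escape X inactivation do not measure that spread.

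The study set the domain architecture of chromosomes side by side in 4 mammals, and the first comparison asked which domain boundaries appeared in both libraries of a species. A boundary is a bin across which contact falls below both flanks, and its depth is the size of that fall. In mouse, the strongest reproducible boundary on autosomes lay next to predicted genes on chromosome 14. The other 4 of the 5 strongest lay, from deeper to shallower, next to the gene of the T cell checkpoint receptor Pdcd1, at Cdc5l, beside the protocadherin alpha cluster, whose genes encode neuronal cell adhesion molecules, and next to the ribosomal protein genes Rps29 and Rpl36al. The longest mouse stretch without a reproducible boundary held the major histocompatibility complex. Across the genome 76.1% of mouse boundaries, 76.8% of rabbit, 78.3% of macaque and 84.4% of dog boundaries had a partner within 1 bin in the other library.

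The deepest mouse boundary lay on chromosome 14 from 19600001 to 19650000 (mm10), next to the predicted genes Gm2237 and Gm5458. Contact across it was 17.3-fold below the lower flank, with a depth of 4.19 in library 1 and 4.04 in library 2 (log2), and 4 bins within 5 bins of it were unusable. The next, on chromosome 1 from 94000001 to 94050000, was 9.51-fold deep and also had 4 unusable bins nearby. Gal3st2c, the sialidase gene Neu4 and Pdcd1 lay within 1 bin of it. On chromosome 17, a 6.06-fold boundary from 45400001 to 45450000 coincided with Cdc5l, which encodes a spliceosome component, and with Spats1. The boundary on chromosome 18 from 36750001 to 36800000 was 5.83-fold deep, with 2 unusable bins nearby. Within 1 bin of it lay Cd14, a co-receptor for bacterial lipopolysaccharide, the histidyl-tRNA synthetase genes Hars and Hars2, and Tmco6, Ndufa2, Ik, Wdr55, Dnd1 and Zmat2. The fifth, on chromosome 12 from 69100001 to 69150000, was 5.34-fold deep and lay next to Rps29, Lrr1, Rpl36al, Mgat2 and Dnaaf2. The strongest boundary of the mouse X, from 72900001 to 72950000, was 3.48-fold deep, with 2 unusable bins nearby. Its neighbours were the centrin gene Cetn2, Nsdhl of cholesterol synthesis, Zfp185 and the predicted gene Gm52416.

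The longest mouse interval between neighbouring reproducible boundaries spanned 8.55 Mb of chromosome 17, from 34050001 to 42600000. Its 220 protein-coding genes included the class II antigen presentation genes H2-Aa and H2-Eb1, the cytokine gene Tnf and a group of olfactory receptor genes. The interval on chromosome 3 from 40500001 to 48900000 was nearly as long, 8.40 Mb, but held only 14 protein-coding genes, among them Pcdh10 and Plk4. A further interval on chromosome 3, of 7.45 Mb from 89250001 to 96700000, held 208 genes, including the Lce and Sprr families, Ivl and Flg of the skin barrier. These intervals were not free of boundary calls in single libraries: the interval on chromosome 17 held 6 calls in library 1 and 3 in library 2 that the other library did not share.

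In the other 3 species the strongest boundaries are given by position, since the gene table used here covers mouse. The deepest of all lay in rabbit on chromosome 4 from 40200001 to 40250000 and was 290.4-fold deep, followed by 138-fold on chromosome 2 from 160600001. The remaining rabbit boundaries of the top 5 were 35.5-fold deep on chromosome 13 from 127900001, 31.9-fold on chromosome 6 from 18250001 and 28.5-fold on chromosome 20 from 12300001. In macaque, chromosome 15 held the deepest pair, 122-fold from 98450001 and 61.6-fold from 101750001. Macaque chromosomes 11 (from 87750001), 9 (from 36700001) and 19 (from 33650001) followed with 40.7-fold, 33.4-fold and 16.5-fold. The deepest dog boundary was 19.4-fold, on chromosome 16 from 41400001. Those on dog chromosomes 4 (from 10450001), 10 (from 1950001), 29 (from 14300001) and 11 (from 60700001) measured 7.81-fold, 7.50-fold, 5.99-fold and 5.93-fold. Unusable bins lay within 5 bins of several of these: 3 each at the 138-fold and 31.9-fold boundaries of rabbit and the 122-fold boundary of macaque, 2 at the 61.6-fold boundary of macaque, and 1 each at the 28.5-fold boundary of rabbit and the 40.7-fold and 33.4-fold boundaries of macaque. The others of the top 5, and all 5 in dog, had 0. On X the strongest boundary was 3.16-fold deep in rabbit (from 20650001), 3.68-fold in macaque (from 6300001) and 4.83-fold in dog (from 44800001, with 2 unusable bins nearby). The longest intervals without a reproducible boundary covered 9.35 Mb of rabbit chromosome 15 from 82300001, 8.40 Mb of macaque chromosome 8 from 1000001 and 5.70 Mb of dog chromosome 26 from 31250001. The next were 7.45 Mb and 6.90 Mb long in rabbit (chromosome 1 from 65700001 and chromosome 8 from 54100001), 7.25 Mb and 6.95 Mb in macaque (chromosome 3 from 21200001 and chromosome 9 from 77700001), and 5.40 Mb each in dog (chromosome 34 from 8450001 and chromosome 23 from 2800001).

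In all, 1857 autosomal boundaries were reproducible in mouse, 1562 in rabbit, 2125 in macaque and 1908 in dog, and the X chromosome added 82, 79, 99 and 93. The median interval between neighbours was 950 kb in mouse, macaque and dog and 1050 kb in rabbit. When 1 library was shifted along its chromosomes, the mean shared share fell to between 14.3% in rabbit and 15.4% in dog (one-sided permutation p = 0.001 in each species, the smallest that 1000 shifts can give). Insulation profiles of the 2 libraries correlated across bins with r = 0.903 in mouse, 0.936 in rabbit, 0.973 in macaque and 0.947 in dog, against at most 0.0396 after shifts (permutation p = 0.001, the smallest possible); bins are not independent replicates. Shallow boundaries were shared less often: of the boundaries of library 1 with a depth between 0.2 and 0.4, 44.7% were shared in mouse, 44.4% in rabbit, 54.2% in macaque and 79.7% in dog. Of those above 0.8 the shares were 88.5%, 91.4%, 87.8% and 93.6%.

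The second comparison asked whether the 4 species differed in how contact fell with distance and in the number and depth of boundaries. On autosomes contact fell 9.15-fold ± 0.751 (SD, n = 2) between 100 kb and 1 Mb in mouse, 7.47-fold ± 1.44 in rabbit, 7.12-fold ± 0.611 in macaque and 8.72-fold ± 1.64 in dog. Liver chromosomes carried 108 ± 5.01 boundaries per 100 Mb in mouse, 102 ± 6.56 in rabbit, 107 ± 1.59 in macaque and 108 ± 6.09 in dog. The median boundary was 0.65 ± 0.03 deep (log2) in mouse, 0.57 ± 0.05 in rabbit, 0.62 ± 0.02 in macaque and 0.64 ± 0.06 in dog. The absolute values depended on the diamond: with 1 Mb to each side the means ran from 64.2 boundaries per 100 Mb in rabbit to 74.8 in mouse, with a median depth between 0.40 and 0.43, and with 250 kb from 148 in rabbit to 151.5 in macaque, with a depth between 0.75 and 0.87. None of these measures separated the species beyond the spread between their libraries.

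The exponent of the fall was -1.06 and -1.02 in the mouse libraries, -1.04 and -0.93 in rabbit, -0.99 and -0.94 in macaque and -1.004 and -1.11 in dog. An exact permutation of the species labels, with n = 2 per species and 105 partitions, gave p = 0.457 for the exponent, p = 0.676 for boundary density and p = 0.352 for median depth. The Benjamini-Hochberg adjusted value over 5 species tests was 0.676 for all 3, in an exact permutation test whose smallest p is 0.00952. The libraries of rabbit alone differed by 0.11 in exponent, and those of dog by 0.11, more than any pair of species means. Simulated maps without boundaries still gave 69 and 74 calls at the depth of macaque 2, on chromosome 1, and at most 1 at the depth of dog 1, so shallow libraries carry more chance calls.

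**Figure D1:**
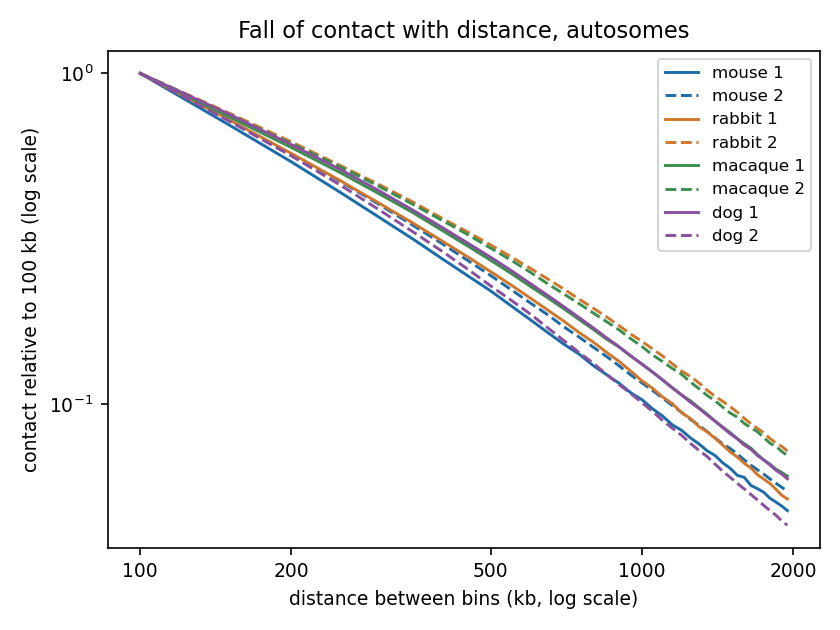
Contact between bins of the same autosome relative to that at 100 kb (y axis, log scale) against the distance between bins in kb (x axis, log scale), a line per library with library 1 solid and library 2 dashed. The lines of the species interleave, and exponents run from -1.11 in dog 2 to -0.93 in rabbit 2.

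**Figure D2:**
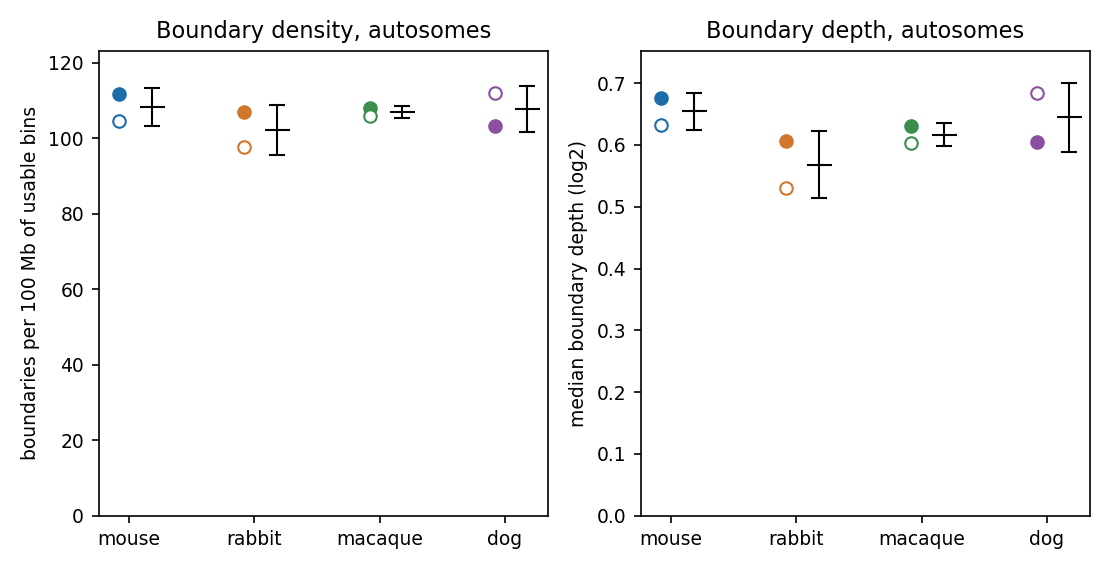
Boundaries per 100 Mb of usable autosomal bins (left) and median boundary depth in log2 (right) in each species. Filled circles are library 1, open circles library 2, and the black marks show the mean with its SD (n = 2), from 102 boundaries per 100 Mb in rabbit to 108 in mouse and dog.

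The X chromosome is shared by the 4 species and was set against the autosomes of the same library. Contact fell less steeply on X in each of the 8 libraries, with exponents between 0.04 and 0.13 higher than on autosomes. The difference was largest in mouse 2, 0.13, against 0.06 in mouse 1, and lay between 0.04 and 0.05 in the other 6 libraries. The exponents of single autosomes had an SD of 0.020 and 0.021 in mouse 1 and 2. This SD was 0.055 and 0.058 in rabbit, 0.050 and 0.044 in macaque, and 0.047 and 0.051 in dog. Outside mouse, X thus differed by about the spread among single autosomes, and whether it stood apart from them was not tested. Boundaries on X were shallower than on autosomes in 7 of 8 libraries, the exception being dog 2. The difference of median depth (log2) was -0.160 in mouse 1 and -0.213 in mouse 2. It was only between -0.058 and -0.030 in the rabbit and macaque libraries and dog 1. X and autosomes of a library were not matched in contacts for this comparison, and fewer contacts can add shallow chance calls. The density of boundaries on X was within 4.41 per 100 Mb of that on autosomes in 7 libraries, while mouse 2 had 86.8 per 100 Mb on X and 105 on autosomes. With all libraries thinned to equal depth on autosomes, mouse 1 had 120.8 on X and 111.8 on autosomes, and mouse 2 had 99.9 and 109. The mean of X minus autosomes in mouse, -0.104, thus averaged differences of opposite sign, and the X of the mouse libraries still differed. This thinning left X of mouse 2 with more contacts than X of mouse 1.

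Over the 4 species means the exponent on X was 0.06 ± 0.02 (SD) higher than on autosomes, with an exact sign-flip permutation p = 0.125, the smallest that 4 species allow (two-sided). The difference did not vary among species beyond the spread between libraries, with p = 0.114 in the exact permutation of species labels (n = 2 per species) and an adjusted p = 0.571. For boundary density on X minus autosomes the same exact permutation test gave p = 0.657 (adjusted p = 0.676), with means of -7.25 ± 14.9 per 100 Mb in mouse, 2.15 ± 3.19 in rabbit, 1.38 ± 2.59 in macaque and -1.98 ± 1.72 in dog (SD, n = 2). This call changed with the settings: in the exact permutation test p was 0.0476 with a minimum depth of 0.4 and 0.0286 with a diamond of 1 Mb. It was 0.0381 in the exact permutation test without mouse 1, where the remaining mouse library was assumed to vary like those of the other species. The level of contact on X relative to autosomes was 0.586 in mouse 1, 1.09 in mouse 2, and between 0.565 and 0.620 in the 6 libraries of the other species.

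**Figure D3:**
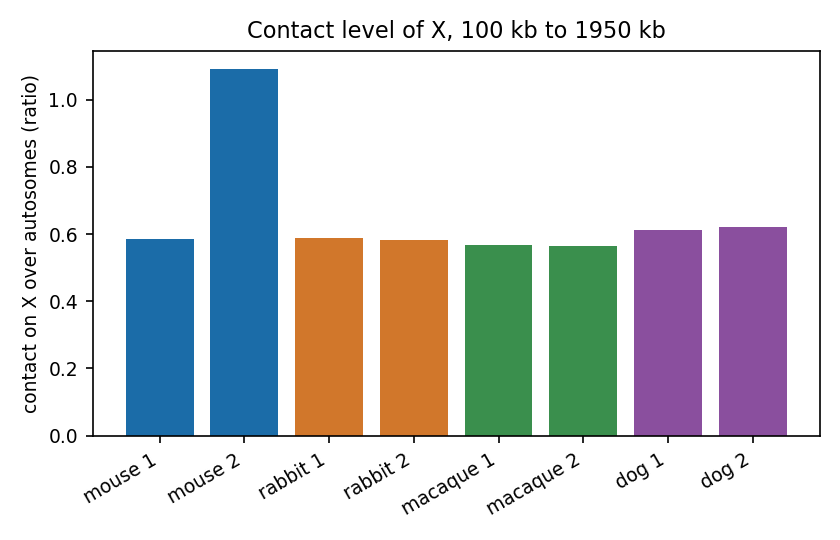
Contact on X over contact on autosomes at equal distance (y axis, ratio averaged over distances from 100 kb to just under 2 Mb) for each of the 8 libraries (x axis). Mouse 2 stands at 1.09 and the other 7 libraries between 0.565 and 0.620.

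The X chromosomes were also searched for stretches with the same order of domains in pairs of species, with autosomes, which are not counterparts of X, as the control. Of neighbouring 10 Mb windows of insulation profile on X, 49.5% found collinear best matches on the X of the other species for rabbit and macaque, 46.7% for rabbit and dog and 41.3% for mouse and rabbit. The shares were 38.3% for mouse and dog, 36.3% for macaque and dog and 32.9% for mouse and macaque. The median autosome gave between 38.1% and 42.5%. With 14 to 18 autosomes as controls, the rank permutation (one-sided) cannot pass 0.05, since its smallest p is between 0.0526 and 0.0667. The larger p of both directions ran from 0.353 for rabbit and macaque to 1 in this permutation (adjusted p = 1 for all 6 pairs), and rabbit and macaque reached the smallest possible 0.0526 in 1 direction. The search recovered 86.9% of windows of the macaque X from its own reversed profile with added noise of 2 SD, but 53.8% when the profile was stretched 1.1-fold and 36.9% when stretched further, against 36.2% on dog autosomes, so chromosomes of different scale were not resolved.

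The last comparison asked which mouse genes start near reproducible boundaries, using gene lists fixed before the data were examined. Protein-coding genes were concentrated there: 17.5% of the 19326 measured genes started within 1 bin of a boundary, against 11.2% on average when boundaries were shifted (permutation p = 0.001, the smallest that 1000 shifts can give, two-sided). Boundary bins held 0.639 gene starts on average and other bins 0.393, a ratio of 1.62, or 1.69 against bins of equal coverage. Hox genes, which pattern the body axis, lay near boundaries most often, and olfactory receptor genes and the clustered protocadherins least often, but the Hox and protocadherin calls were lost when the clustering of these genes was taken into account. Genes of hepatocytes and of the other liver cell types were not set apart from the remaining genes.

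Of the 39 Hox genes, 19 (48.7%) started within 1 bin of a boundary, an odds ratio of 4.49 against all other genes (Fisher's exact test, two-sided, adjusted p = 3.45e-05 over 9 lists). All 11 Hoxa genes and 8 of the 9 Hoxd genes were among them, and none of the 10 Hoxb or 9 Hoxc genes. A boundary 1.87-fold deep lay inside the Hoxa cluster on chromosome 6 from 52200001 to 52250000, over Hoxa5, Hoxa6, Hoxa10 and Hoxa11. The boundary in the Hoxd cluster on chromosome 2 was only 1.23-fold deep and started at 74.65 Mb. Because these genes stand in clusters, the shift test, which keeps neighbours together, gave an adjusted p of 0.0899 (permutation). Counted once per bin, 5 of 13 bins with Hox genes were near a boundary (odds ratio 2.91, Fisher's exact test, adjusted p = 0.192), and with a minimum depth of 0.4 the odds ratio was 2.17 (Fisher's exact test, adjusted p = 0.124).

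None of the 51 measured genes of the clustered protocadherins started within 1 bin of a boundary (Fisher's exact test, adjusted p = 0.000348; shift permutation, adjusted p = 0.261; 13 bins counted once, Fisher's exact test, adjusted p = 0.322). The 3 clusters filled chromosome 18 from 36.9 to 37.8 Mb, between the boundary 5.83-fold deep next to Cd14 and Hars and another, 2.14-fold deep, that started at 37.90 Mb. The nearest members, Pcdhgc3, Pcdhgc4 and Pcdhgc5, started 100 kb from the latter, and Pcdha1 started 150 kb from the former. The 5.83-fold call lay beside a gap: 2 unusable bins followed the boundary bin. Insulation in the bin of Pcdha1 (-2.22 and -2.96) was nearly as low as in the boundary bin (-2.34 and -3.04). Whether the count of 0 depended on this call was not tested. Within 2 bins the count was 3 of 51, namely Pcdhgc3, Pcdhgc4 and Pcdhgc5 near the 2.14-fold boundary.

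**Figure D4:**
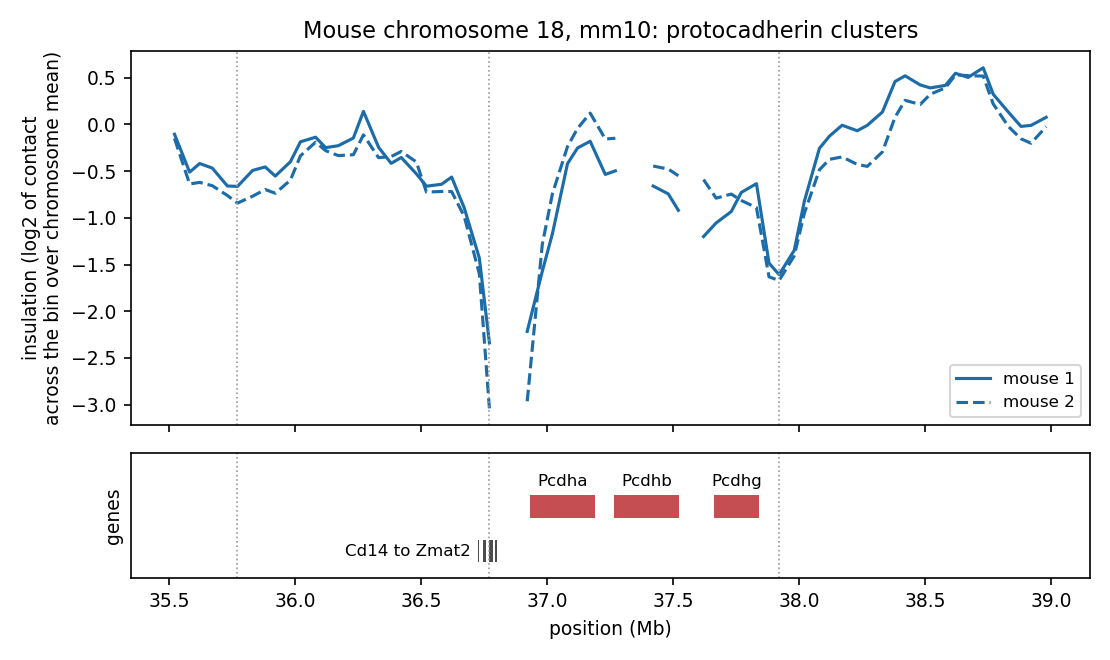
Insulation in the 2 mouse libraries (top, log2 of contact across each 50 kb bin over the chromosome mean, library 1 solid and library 2 dashed) and genes (bottom) along chromosome 18 in Mb (mm10). Dotted lines are reproducible boundaries, gaps in the lines are unusable bins, and the 3 protocadherin clusters lie between the 5.83-fold boundary and the 2.14-fold boundary.

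Olfactory receptor genes lacked the concentration at boundaries seen for other genes: 93 of 1026 (9.06%) started near one, within the 5.85% to 17.3% (mean 11.4%) that shifted boundaries gave for this list (permutation p = 0.228). Against all other genes the odds ratio was 0.454 (Fisher's exact test, adjusted p = 3.44e-14). The list lay -8.46 percentage points from all genes, against -4.87 to 5.92 points after shifts (shift permutation, adjusted p = 0.009). Olfr9 on chromosome 10 and Olfr543, Olfr544 and Olfr545 on chromosome 7 started within a boundary bin. Of the genes named as ribosomal proteins, 25 of 95 (26.3%) started near a boundary, an odds ratio of 1.69 that missed the threshold in Fisher's exact test (adjusted p = 0.0671) and passed it in the shift permutation (adjusted p = 0.036). Rps23 (boundary depth 1.86, log2), Rplp1 (1.39), Rpl34 (1.19) and Rps15a (1.02) started within a boundary bin. The list, taken by symbol, held 10 genes that encode no ribosomal protein, such as the kinase genes Rps6ka3 and Rps6ka5, and without them the count was 23 of 85 (odds ratio 1.75, Fisher's exact test, adjusted p = 0.0687). With the boundaries of mouse 2 alone, 36 of 95 were near (odds ratio 2.09, Fisher's exact test, adjusted p = 0.00181), and with those of mouse 1 alone 28 of 95 (odds ratio 1.47, adjusted p = 0.191). Counted once per bin, 24 of 92 bins were near (odds ratio 1.65, Fisher's exact test, adjusted p = 0.179).

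Of the 38 hepatocyte genes, 5 started near a boundary, among them Ahsg and Hp, which encode abundant plasma proteins, Cyp2e1, which encodes a drug-metabolising enzyme, and Otc of the urea cycle (13.2%, odds ratio 0.713). Among 14 Kupffer cell and leukocyte genes there were 3, the macrophage marker Adgre1, the leukocyte marker Ptprc and Cd68 (odds ratio 1.28). Among 14 endothelial and stellate genes there were 2, the VEGF receptor gene Kdr and Reln (odds ratio 0.784), with Dcn and Col3a1 at 100 kb. Epcam was the only 1 of 6 cholangiocyte genes (odds ratio 0.941), with Krt7 at 100 kb, Krt19 at 200 kb and Cftr at 250 kb. Stmn2 and Syt1 were 2 of 12 neuronal genes (odds ratio 0.941), with Snap25 and Tubb3 at 100 kb. All 5 of these lists had an adjusted p of 1 in Fisher's exact test and of 0.728 or 1 in the shift permutation. The gene table gives no strand, so the lower coordinate of a gene stood for its start.

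**Figure D5:**
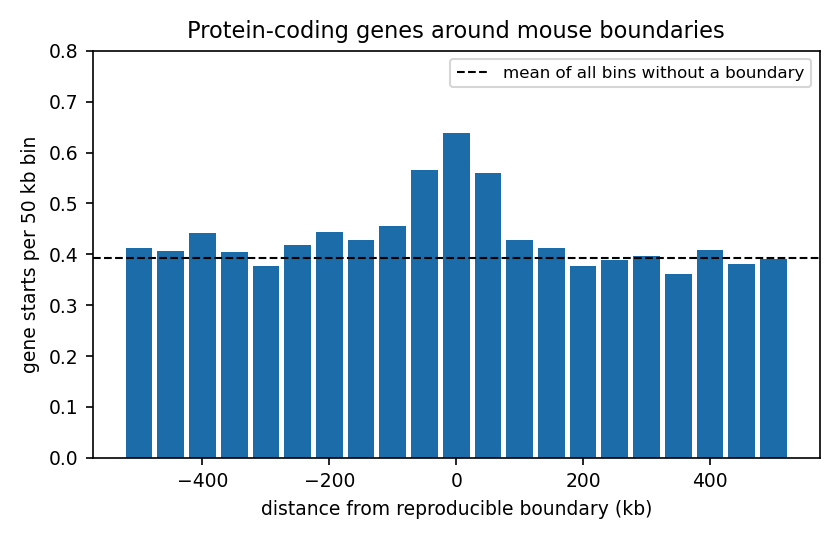
Protein-coding gene starts per 50 kb bin (y axis) against the distance from reproducible mouse boundaries in kb (x axis). Bars are means over boundaries, with 0.639 at the boundary bin, and the dashed line is the mean of bins without a boundary, 0.393.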

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

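Contacts within a single 50 kb bin lie outside every comparison above, and they formed a signal in each library. They numbered 2.55 and 6.52 M in mouse 1 and 2 (2.548 and 6.524 before rounding), 2.32 and 1.71 M in rabbit (2.318 and 1.711), 2.63 and 1.39 M in macaque (2.628 and 1.392), and 5.03 and 4.14 M in dog (4.145 for dog 2 before rounding). In a test added after the data were seen, their share of contacts did not differ among species beyond the spread between libraries (exact permutation p = 0.533, two-sided in effect because the statistic is an F ratio). No explanation of these contacts was tested.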

How the results depend on the processing

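The stretched X profile, the omission of deep or gap-adjacent boundaries and 4 changes to the gene lists were chosen after the data were seen. Across the main comparisons whose tests could pass the threshold, 158 alternatives kept the side of the threshold and, for the odds ratios of gene lists, the direction; 4 became significant, 3 lost significance and 12 reversed, all 12 in lists of 6 to 38 genes past no threshold in any alternative. Of the means per species 101 stayed within the spread between libraries (SD, n = 2) and 55 moved. Means with a library left out are counted among the 101 and could only stay. With 2 libraries, that shift is always smaller than the SD. The reversed odds ratios were, within 2 bins, 1.46 for hepatocyte, 0.766 for Kupffer cell and leukocyte, 1.12 for endothelial and stellate, 1.405 for cholangiocyte and 2.01 for neuronal genes. At a minimum depth of 0.4 they were 0.918 for Kupffer cell and leukocyte and 1.101 for both cholangiocyte and neuronal genes, and with the upper gene coordinate 0.368 for Kupffer cell and leukocyte and 1.595 for neuronal genes. With boundaries of a single mouse library the range was 0.929 to 2.64 for Kupffer cell and leukocyte and 0.929 to 1.408 for endothelial and stellate genes. Exact permutation p across species stayed between 0.286 and 0.733 for the decay exponent, 0.467 and 1 for boundary density, 0.143 and 0.724 for depth, and 0.114 and 0.610 for the exponent on X. For boundary density on X the exact permutation p was 0.0476 at a minimum depth of 0.4 and 0.0286 with a diamond of 1 Mb, and 0.0381 to 0.886 when single libraries were left out, lowest without mouse 1; the cause was not tested. Profile correlations stayed between 0.877 and 0.974, shared boundaries between 53.3% and 89.0%, and collinear X windows between 15.4% and 60.5% (permutation p 0.118 to 1); the 42 alternatives of the last say nothing about stability, since their test cannot pass the threshold. The Hox odds ratio fell to 2.17 at a minimum depth of 0.4 and, with fewer units tested, to 2.91 once per bin; protocadherins once per bin gave 0 near boundaries of 13 bins (Fisher's exact test, adjusted p = 0.322). The ribosomal odds ratio was 1.47 to 2.09 with boundaries of a single mouse library. Permuting within replicate number gave exact p = 0.583, 0.667, 0.458, 0.125 and 0.792 for the 5 species tests. Replicate agreement cannot be had with a library left out. Not run were compartment strength and agreement, CTCF motif density and genes of the same symbol. At the lowest depth, 3.16 contacts per pair of bins, shallow boundaries include chance calls.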

Other observations

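The tests of tRNA genes counted once per bin, of a second X copy, of depth for X boundaries, of a difference of the whole mouse library and of a uniform background were chosen only after the results were seen. Genes can sit in domains with many or few contacts at long range, and the mouse gene lists were compared in the log2 ratio of contacts at 1 to 2 Mb to contacts at 100 to 500 kb. Neuronal genes had a median 0.64 above that of all genes (12 genes, shift permutation, adjusted p = 0.0135), and clustered protocadherins, a family of neuronal adhesion genes, lay at -0.56 relative to all genes (24 genes, shift permutation, adjusted p = 0.009). Olfactory receptor genes lay 0.236 above all genes (949 genes, shift permutation, p = 0.0180, adjusted p = 0.0540). Ribosomal protein genes lay at -0.02 (shift permutation, adjusted p = 0.890). The prediction that olfactory receptor and neuronal genes have more and ribosomal protein genes fewer long-range contacts therefore failed for the ribosomal list. The prediction named no adjustment: the olfactory receptor list passed 0.05 in the shift permutation before adjustment and missed it after adjustment. Of the 362 tRNA genes of mouse, 12.7% lay within 1 bin of a boundary, against 11.3% on average after shifts (permutation p = 0.355, one-sided). Counted once for each of the 150 bins that hold them, 17.3% lay near, against 11.2% after shifts (permutation p = 0.0240, one-sided). The comparison was with shifts alone: of protein-coding genes, counted singly, 17.5% lay near a boundary. The planned prediction that tRNA genes mark boundaries, which was on genes, was not met.

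The mouse X differed between the libraries, with a level relative to autosomes of 0.586 in mouse 1 and 1.09 in mouse 2. Against the bias model, the ratio of these levels stayed at 1.86 without the bias correction. Against a difference of the whole library, the depth of boundaries on X changed by -0.342, below the -0.19 to -0.09 of every autosome at matched contacts. These boundaries were picked in mouse 1 for a depth of at least 0.4, which favours a fall in mouse 2 on any chromosome. Over all X boundaries at matched contacts the median depth was 0.516 in mouse 1 and 0.424 in mouse 2, a smaller fall. Autosomes were not compared in that way. A second copy of X in mouse 2 may explain the level. Over X bins the ratio of mouse 2 to mouse 1 had a median of 1.788 and a 5th percentile of 1.436. Over autosomal bins the median was 1.013 and the 95th percentile 1.246, with single autosomes between 0.9801 and 1.052. The difference in level thus covered most of X and was not seen on any autosome. The share of X bins with a ratio between 1.6 and 2.4 was 76.7%, under the 80% that the test required. From the 5th to the 95th percentile, X bins spread from 1.436 to 2.268 and autosomal bins from 0.7778 to 1.246. Spread between bins can thus carry X bins out of the range, so the shortfall does not argue against a second copy. The labels give no sex, so a second copy stays open. For the level, thinning left the ratio at 1.87 but lowers X and autosomes alike and so decides nothing. The libraries of the other species argue against depth as its cause. They spanned 3.16 to 15.5 contacts per pair of bins, yet their levels lay between 0.565 and 0.620. Dog 1, at 15.5 against 13.3 in mouse 2, stood at 0.612. For the number of X boundaries depth stays open: after thinning to the contacts of mouse 1 the difference was -10.6 per 100 Mb (range -16.6 to -6.51 over 20 thinnings). Boundaries near listed genes that escape X inactivation, such as Kdm6a and Ddx3x, lost 0.207 less depth than the other X boundaries (5 of 101 boundaries, permutation p = 0.0237, one-sided). This met the prediction for a second, inactive X with weaker domains. However, the maps of this test were not matched: X held 1.69 contacts per pair of bins in mouse 1 and 11.3 in mouse 2. Its boundaries were picked by their depth in mouse 1, and the 5 near escape genes come from 1 pair of libraries.

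Boundaries at least 4-fold deep numbered 24 in rabbit and 26 in macaque, and 12 and 13 of them were deeper than 8-fold, against 2 of 30 in mouse and 1 of 28 in dog. Contact across the 50 in rabbit and macaque at 1 to 2 Mb was a median 16.4% of that expected (quartiles 9.57% and 37.8%), against 92.8% at ordinary boundaries, and 60% of them had an unusable bin within 5 bins, against 9.07%. Wrong joins of the assemblies or gaps may account for many of them. However, these boundaries were chosen for low contact across the same bins in the same libraries, and ordinary ones for a smaller depth. The contrast in contact at 1 to 2 Mb was thus partly set in advance. It cannot tell a wrong join from a true deep boundary. The 290.4-fold boundary of rabbit chromosome 4 had 0 unusable bins within 5 bins. This count cannot exclude a gap there that is too short to make a 50 kb bin unusable. In mouse and dog the contact across was 42.5% and 44.2%, and an unusable bin lay nearby at 36.7% of deep mouse boundaries, against 8.42% of ordinary ones, and at 7.14% of deep dog boundaries, against 7.08%. No biological explanation was tested, and the species cannot be separated from their assemblies in this design.

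In each of the 4 species the library with the steeper decay had the deeper boundaries, which in an exact sign test over the 4 pairs gives p = 0.125, the smallest that 4 pairs allow (two-sided, 5 relations examined). Depth was excluded as the cause, since the order was kept in 4 of 4 species after thinning. A uniform background of random contacts could flatten decay and boundaries together, but adding it reached the other library within the set margin in 2 of 4 species (28.3%, 51.1%, 59.1% and 40.8% of the difference in mouse, rabbit, macaque and dog). In its favour, the library with the flatter decay had the higher share of contacts between chromosomes in 4 of 4 species (26.1% against 21.7%, 22.8% against 16.7%, 21.04% against 18.2% and 31.8% against 28.6%). Over all 8 libraries the relation of exponent and that share was weak and ran the other way (Pearson r = -0.25). The uniform background therefore stays open. No biological explanation was tested.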
